A study of Mus musculus with 8 samples.

How the data were processed

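RNA-seq values were given for 8 libraries, 4 labelled PBS and 4 labelled rFGF4 (recombinant fibroblast growth factor 4). Per the labels, the RNA came from C57BL/6 mouse skin in the 2 mm zone round wounds at day 6. The expression table used here did not match that description. All 58304 gene identifiers kept from it were human Ensembl identifiers and 0 were mouse identifiers. Its gene symbols were human, and its coordinates were those of human genes. Its columns were named C and FGF4 with the numbers of the replicates, and they were matched to the samples by these names alone. Values are therefore given for "the libraries labelled PBS" and "the libraries labelled rFGF4", and no statement is made on mouse wounds. Which cells the table describes is not given in the sources used here.

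The submitters' processing notes name HISAT2 2.0, an aligner, and StringTie 1.3.0, which assembles and quantifies transcripts, without saying which step each was used for. The genome build and the annotation are not given in the sources used here, so coordinates below are printed as the table gives them. The authors deposited 2 columns per library, per the file headers. The first holds FPKM (fragments per kilobase of gene, scaled to the mapped fragments), the unit in which the authors deposited them, per the file headers, with 0.0001 in place of 0. The second holds counts. The deposited counts are whole numbers but behave as estimated counts of the kind StringTie's coverage gives. Low values piled up at 4, 8 and 12, with 9781 entries at 4 against 3485 at 3 and 1977 at 5. No such excess over the value below was seen at 16, with 1476 entries against 1553 at 15. The values 1 and 2 held 5170 and 4545 entries. Within a gene, the ratio of count to FPKM was constant over libraries after scaling (SD 0.0013 on the log2 scale over 11103 genes with more than 200 counts in every library), so both columns carry the same measurement. Whether counting used the strand is not given in the sources used here. Overlapping and antisense genes, pseudogenes and near-identical copies can therefore share counts.

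The planned test was limma on log2(FPKM + 1), with edgeR written in its place for a table that held counts. Counts were present, so edgeR 4.0.16 in R 4.3.3 was used on the whole-number counts as deposited, with TMM scaling and the quasi-likelihood test (glmQLFit and glmQLFTest). Genes with a mean FPKM of at least 1 over the 8 libraries were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are rFGF4 over PBS. The SE of a log2 fold change is the size implied by the test statistic. Genes of the Y chromosome, XIST and TSIX were left out of every step because the values are human, which removed 521 of 58825 genes. Levels are CPM (counts scaled to the library's total over the tested genes) with TMM factors, as mean ± SD (n = 4).

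Gene lists were written before the data were examined, as 758 mouse symbols in 46 lists. After the table was seen to be human, they were carried over by writing the symbols in capitals, with 33 replaced by hand, and 739 had an entry. Lists with at least 4 tested members were compared with all other tested genes by camera in limma 3.58.1 on log2(FPKM + 1), with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which tests whether a list moved one way without comparing it with other genes, were run beside it. The named genes were set by a rule written before the data were examined. It took (a) the members of the FGF ligand, FGF receptor and FGF and ERK target lists past the threshold, with FGF4, DUSP6, ETV4, ETV5, SPRY2, SPRY4, SNAI2 and GSK3B in any case. It took (b) the 10 largest changes in each direction among genes past the threshold whose groups did not overlap and whose mean FPKM was at least 1 in the higher group, and (c) up to 4 members of each list with the smallest p in its direction. Part (b) excludes unnamed gene models; human clone names were added to that exclusion after the table was seen. KRT5, KRT14, MYC, CDH1, CDH5, CCL2, IL23A, JUN, ITGA3, WNT10A, BMP1, CSF1 and ERBB2, members of the lists, and PI3 and IL32 were named outside the rule, after their values were seen. So were COL1A1, COL1A2, COL3A1, HBB and ACTA1.

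The libraries held 62044121 to 73680756 counts. From the pile-up, 1 fragment was taken to be worth about 4 counts, although lower values were common. The floor was set at 3 fragments, or 12 counts, which is 0.163 to 0.193 CPM. For the floor, CPM was scaled to the total over all genes kept, without TMM factors. The method was tested on simulated counts drawn from the means and library sizes of the 11536 tested genes, with 200 genes changed. It recovered 4% of the genes changed 1.25-fold, 26% at 1.5-fold, 80% at 2-fold and 94% at 4-fold, with 2 false calls. A raised list was called and 0 unchanged lists were, by camera on log2 CPM. The simulated genes were drawn independently, so the preset correlation between genes was not tested. The recovered shares hold for that simulation, and smaller changes passed in the data. Intervals treat genes as independent draws and floors cover counting error only. Neither covers the spread between libraries.

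Alternatives were other pseudocounts, filters, scalings, variance models and thresholds, the replicate number as a block, and each library left out in turn. DESeq2 1.42.0, edgeR with robust dispersions or with median-of-ratios factors, edgeR with the library total alone, filterByExpr, counts divided by 4, camera with a variance trend or on log2 CPM, and a fit without genes in which 1 library stood apart were chosen after seeing the data. Keeping limma on log2(FPKM + 1), the test planned for a table without counts, as an alternative was also decided then. The samples share replicate numbers, but nothing in the labels says that a number marks the same animal, culture or day, so the test had no block. Nor do the labels say whether samples of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. No human genome was used here, so GC content was not examined.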

Results

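The study set out to compare gene expression between wounds given rFGF4, a recombinant fibroblast growth factor, and wounds given PBS. RNA-seq was reported for 8 libraries, 4 in each group, with 62044121 to 73680756 counts per library. The table analysed here holds human genes, although the labels describe mouse skin. The groups below are those of the column names, and no value below is attributed to mouse wounds. Of 58304 genes, 28630 had 0 counts in every library and 11536 passed the filter on low values.

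The libraries carried an epithelial profile. Of the basal keratinocyte list, 14 of 14 members were at a mean FPKM of at least 1. KRT5 and KRT14, the keratin pair of basal keratinocytes, stood at 4881 ± 605 and 2949 ± 188 CPM in the PBS libraries (mean ± SD, n = 4). PI3 (7.55 ± 1.5 CPM) and IL32 (4.8 ± 0.55 CPM), which have no mouse counterpart and were named after their values were seen, were both counted in the PBS libraries. Of the wound-activated keratinocyte list 15 of 20 members, of the epithelial junction list 16 of 18 and of the differentiated epidermis list 6 of 19 were at that level. For lists of other cell types it was 1 of 20 for skeletal muscle, 1 of 15 for dermal fibroblasts, 3 of 16 for neutrophils and 2 of 18 for macrophages. It was 5 of 13 for myofibroblasts, 9 of 26 for fibrillar collagens and matrix assembly, 4 of 13 for dendritic cells, 7 of 23 for endothelium and angiogenesis and 4 of 16 for adipocytes. The T and NK cell (19 members), mast cell (8), erythrocyte (7), melanocyte (8), lymphatic (7), pericyte (9), muscle regeneration (12) and alternatively activated macrophage (10) lists had 0 members at that level, and the B cell list had 1 of 9. The Schwann cell list had 3 of 12. Lists with fewer than 4 members at that level were not tested between the groups. The neutrophil members measured were S100A8, S100A9 and LCN2, which keratinocytes also express. COL1A1, COL1A2 and COL3A1 were not among the matrix assembly members at that level. The highest FPKM in any library was 0.303 for COL1A1, 0.046 for COL1A2, 0.407 for COL3A1, 0.067 for HBB and 0.029 for ACTA1.

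**Figure D1:**
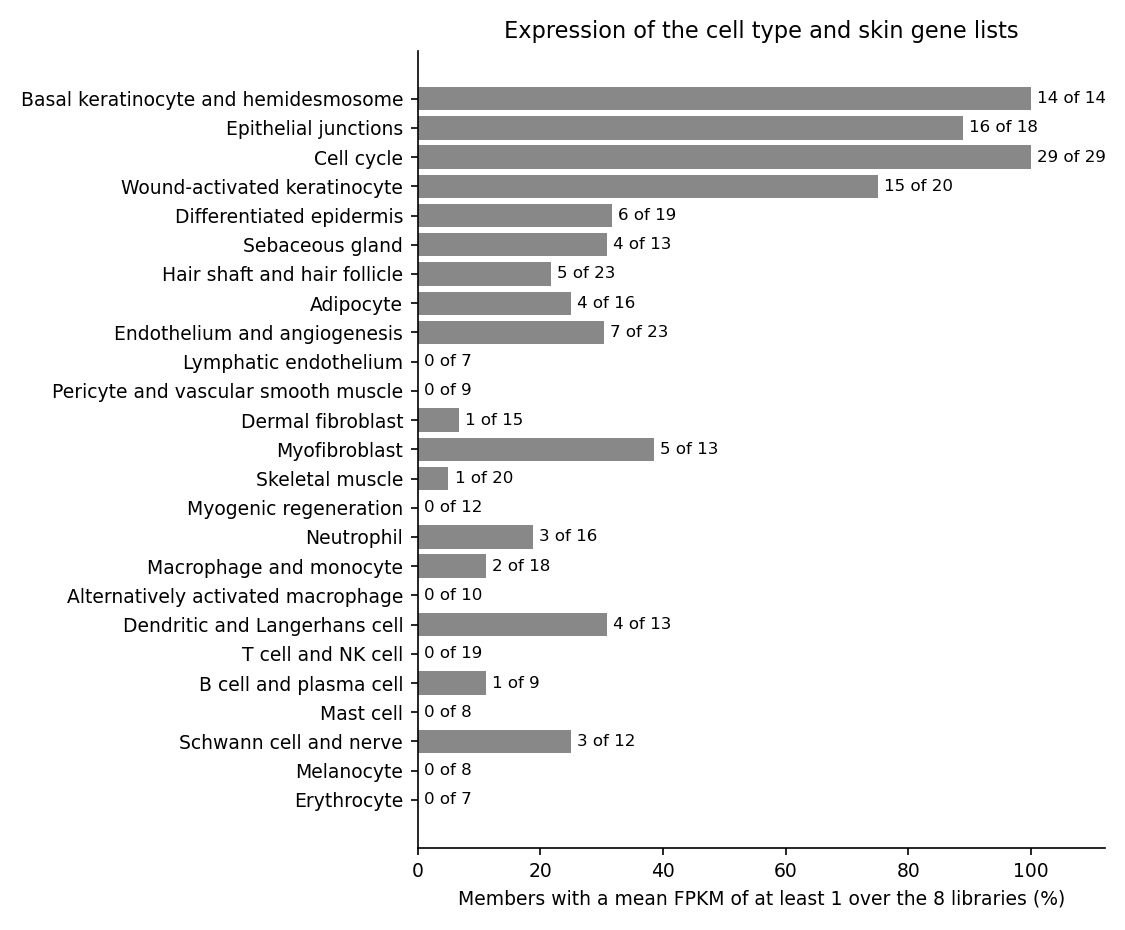
Share of the members of each cell type or skin list with a mean FPKM of at least 1 over the 8 libraries, in percent, with the number of such members beside each bar. The basal keratinocyte list reached 14 of 14, while the T and NK cell list had 0 of 19 and the erythrocyte list 0 of 7.

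The feedback and target genes of FGF and ERK signalling were higher in the libraries labelled rFGF4. DUSP6, a phosphatase that acts on ERK, stood at 35.1 ± 4.12 CPM in the PBS libraries and 174 ± 21.7 CPM in the rFGF4 libraries, a log2 fold change of 2.31 (SE 0.12, edgeR adjusted p = 0.000115). ETV5 and ETV4, transcription factors induced by FGF signalling, rose by 2.33 (SE 0.16, adjusted p = 0.00026) and 1.41 (SE 0.08, adjusted p = 0.000115). FOSL1, an AP-1 subunit, rose by 2.08 (SE 0.14), DUSP4 by 1.78 (SE 0.12) and IER3 by 1.32 (SE 0.10). Of the 15 tested members of the list, 13 rose, 1 fell and 1 did not pass the test, with 13 and 1 also when adjusted over the list alone. The list was called as higher by camera (adjusted p = 2.84e-13), with adjusted p = 0.0724 with an estimated correlation. Among the other members that rose were PHLDA1 (1.36), SPRY2 (1.09), SPRY1 (0.94), DUSP5 (0.90), SPRED1 (0.67), SPRED2 (0.66) and CCND1 (0.51). EGR1, an immediate early transcription factor, fell by 0.63 (SE 0.12, adjusted p = 0.0141). MYC did not pass, with a log2 fold change of −0.46 (SE 0.61), and stood at 6.65 CPM in rFGF4 replicate 3 against 42.7 to 98.0 CPM in the other libraries of its group. ETV5 (3.81 CPM) and SPRY2 (2.23 CPM) in PBS replicate 2, DUSP5 in PBS replicate 1 (4.23 CPM) and PHLDA1 in PBS replicate 4 (70.2 CPM) lay below the other PBS libraries. SPRY4, below the filter on low values, stood at 0.467 ± 0.090 and 3.10 ± 0.25 CPM. FGF4 itself had 0 counts in all 8 libraries. The call for SPRY2 (adjusted p = 0.0452) ended without PBS replicate 1 or 4, or rFGF4 replicate 1, 2, 3 or 4, and that for PHLDA1 without PBS replicate 2 or 3 or rFGF4 replicate 2. SPRED1 and SPRY2 did not pass with limma on TPM, nor SPRY2 with a filter at a mean FPKM of 0.1, no filter or filterByExpr.

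**Figure D2:**
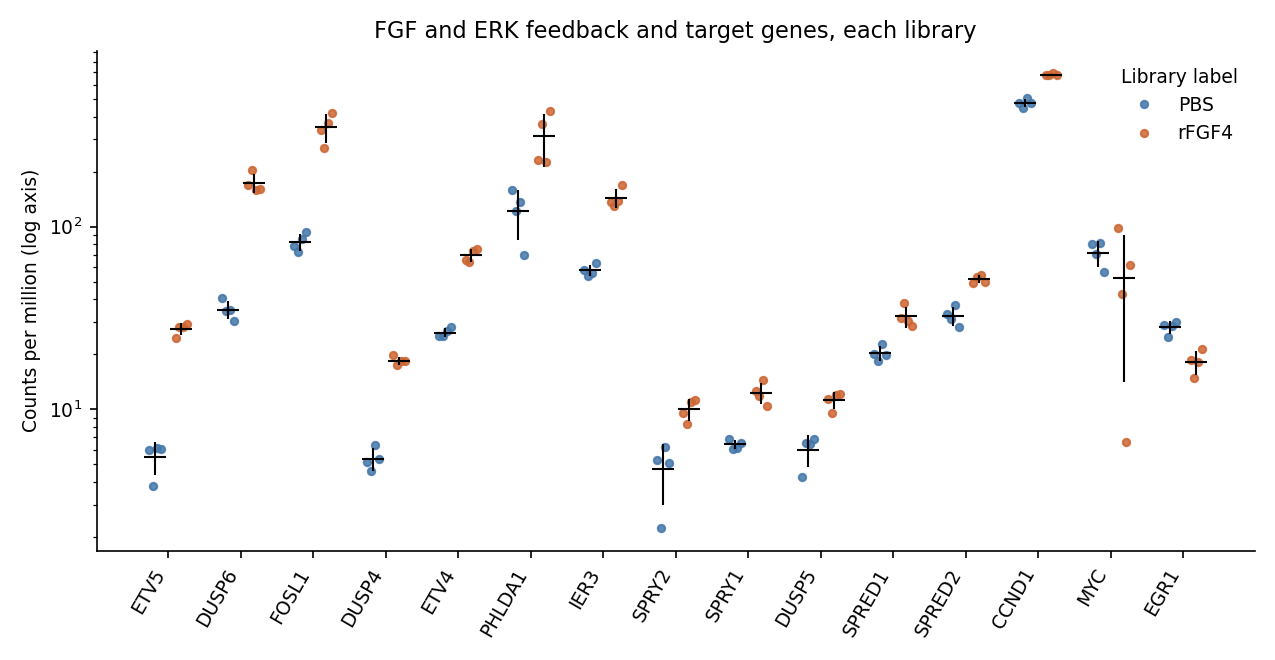
CPM on a log axis for the 15 tested FGF and ERK feedback and target genes in each of the 4 PBS and 4 rFGF4 libraries. Horizontal ticks are group means and vertical lines are SDs. For 13 genes the rFGF4 libraries were higher, with DUSP6 at 174 against 35.1 CPM.

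The FGF receptor list moved the other way. FGFR3 fell by 1.03 (SE 0.18, adjusted p = 0.00979), from 28.8 ± 6.14 to 14.1 ± 2.45 CPM, and SDC4, a heparan sulfate proteoglycan, fell by 0.44 (SE 0.06). Of 5 tested members 2 fell, also when adjusted over the list alone, and 3 did not pass. The list was called as lower (camera adjusted p = 0.00439), with adjusted p = 0.0977 with an estimated correlation. None of the 13 FGF ligands reached a mean FPKM of 1. Of the p38, GSK3 beta and Snail family list, 0 of 9 tested members passed (camera adjusted p = 0.788), and 0 also when adjusted over the list alone. SNAI2 had a log2 fold change of 0.19 (SE 0.30) and GSK3B had −0.10 (SE 0.07). SNAI2 was low in rFGF4 replicate 2, at 31.7 CPM with the others of its group at 67.7 to 71.2 CPM. It was also low in PBS replicate 3, at 30.25 CPM with the others of that group at 55.71 to 64.37 CPM.

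The pro-inflammatory cytokine list and the endothelium and angiogenesis list were called as higher in the libraries labelled rFGF4. VEGFA, which promotes vessel growth, rose by 1.29 (SE 0.05, adjusted p = 5.22e-05), from 73.7 ± 1.43 to 180 ± 8.34 CPM, and VEGFC rose by 0.80 (SE 0.14). Of the endothelium and angiogenesis list, 2 of 7 tested members rose (3 adjusted over the list alone) and the list was called as higher (camera adjusted p = 0.00235), with adjusted p = 0.0977 with an estimated correlation. VEGFA and VEGFC are secreted ligands, and the member past the threshold over the list alone was CDH5 (0.33, SE 0.11), a cadherin of endothelial cells. The cytokine CXCL1 rose by 1.31 (SE 0.11), IL1A by 1.03 (SE 0.12) and IL1B by 0.95 (SE 0.07), and IL23A (1.02) and LIF (0.59) rose too. These were 5 of 6 tested members of the pro-inflammatory list, 5 also when adjusted over the list alone (camera adjusted p = 4.54e-05), with adjusted p = 0.0769 with an estimated correlation. CCL2 did not pass (−0.23, SE 0.12). The EGF receptor ligands AREG, HBEGF and TGFA rose by 1.58, 0.88 and 0.74, and PDGFB by 0.74, while CSF1 fell by 0.69 and ERBB2 by 0.34. That growth factor list, with 4 of 10 higher and 2 lower (4 and 3 adjusted over the list alone), was not called (camera adjusted p = 0.0578).

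The epithelial junction and interferon response lists were called as lower. CLDN1, a tight junction protein, fell by 0.58 (SE 0.06, adjusted p = 0.000819), from 482 ± 17.6 to 324 ± 16.0 CPM. The desmosomal cadherin DSC2 fell by 0.70 (SE 0.11), the tight junction protein OCLN by 0.54 (SE 0.09) and PERP by 0.30 (SE 0.06). Of 16 tested members of the epithelial junction list, 6 fell (7 adjusted over the list alone) and 10 did not pass, among them CDH1 (−0.25, SE 0.16). The list was called as lower (camera adjusted p = 0.000644), with adjusted p = 0.0769 with an estimated correlation. The call for PERP ended without PBS replicate 2 or rFGF4 replicate 1. Of the interferon list, 4 of 11 tested members fell, the same number when adjusted over the list alone. OASL fell by 0.58 (SE 0.10), IFI44 by 0.41 (SE 0.09), IFIT1 by 0.40 (SE 0.07) and IFIT3 by 0.31 (SE 0.05). The list was called as lower (camera adjusted p = 0.000121), with adjusted p = 0.0769 with an estimated correlation. With limma on TPM, IFIT1, IFIT3 and IFI44 did not pass, and the call for IFI44 also ended without PBS replicate 1, 2 or 3 or rFGF4 replicate 1 or 3.

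The other 5 lists called by camera had 0 to 4 members past the threshold. Of 24 cytoskeleton and migration genes 4 rose, namely RAC2 (0.56), FSCN1 (0.51), PXN (0.32) and CTTN (0.28), with 4 adjusted over the list alone (camera adjusted p = 0.0478; adjusted p = 0.211 with an estimated correlation). Of 29 cell cycle genes 2 fell, KIF20A (−0.33) and CCNB2 (−0.25), and 2 when adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.329 with an estimated correlation). Of 16 NRF2 pathway and antioxidant genes CAT (−0.43) and GCLC (−0.45) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.211 with an estimated correlation). None of the 25 nuclear genes of oxidative phosphorylation passed, in either adjustment, with a list median of −0.09 (camera adjusted p = 0.0226; adjusted p = 0.62 with an estimated correlation). In the adipocyte list, ACSL1 (−0.78) and FABP4 (−0.51) fell among 4 tested members, 2 also when adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.211 with an estimated correlation). ACSL1 activates fatty acids in many cell types. The migration call ended without PBS replicate 1 or 4 or rFGF4 replicate 1, 2 or 3, and the oxidative phosphorylation call without PBS replicate 2 or 4 or rFGF4 replicate 1, 2 or 3. The adipocyte call ended without PBS replicate 1 or 4 or rFGF4 replicate 1 or 2, and the NRF2 call without PBS replicate 4. The migration call also ended after median-of-ratios scaling or quantile normalisation of FPKM, by fry and by camera on log2 CPM, and was lost under 11 of 22 settings run. The oxidative phosphorylation call also ended by fry and by camera on log2 CPM (8 of 22), and the adipocyte call with a filter at a mean FPKM of 0.1 and with no filter (8 of 22). Of the genes, FABP4 did not pass with any 1 library left out, CCNB2 did so only without rFGF4 replicate 4, and GCLC did not pass without PBS replicate 2 or 3 or rFGF4 replicate 3. PXN and RAC2 did not pass without PBS replicate 1, 2 or 3 or rFGF4 replicate 1 or 3, nor RAC2 without rFGF4 replicate 4. KIF20A, CTTN and GCLC did not pass with limma on TPM, nor PXN and RAC2 with no filter on low values, and CCNB2 and FABP4 did not with a filter at a mean FPKM of 0.1, no filter or filterByExpr.

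**Figure D3:**
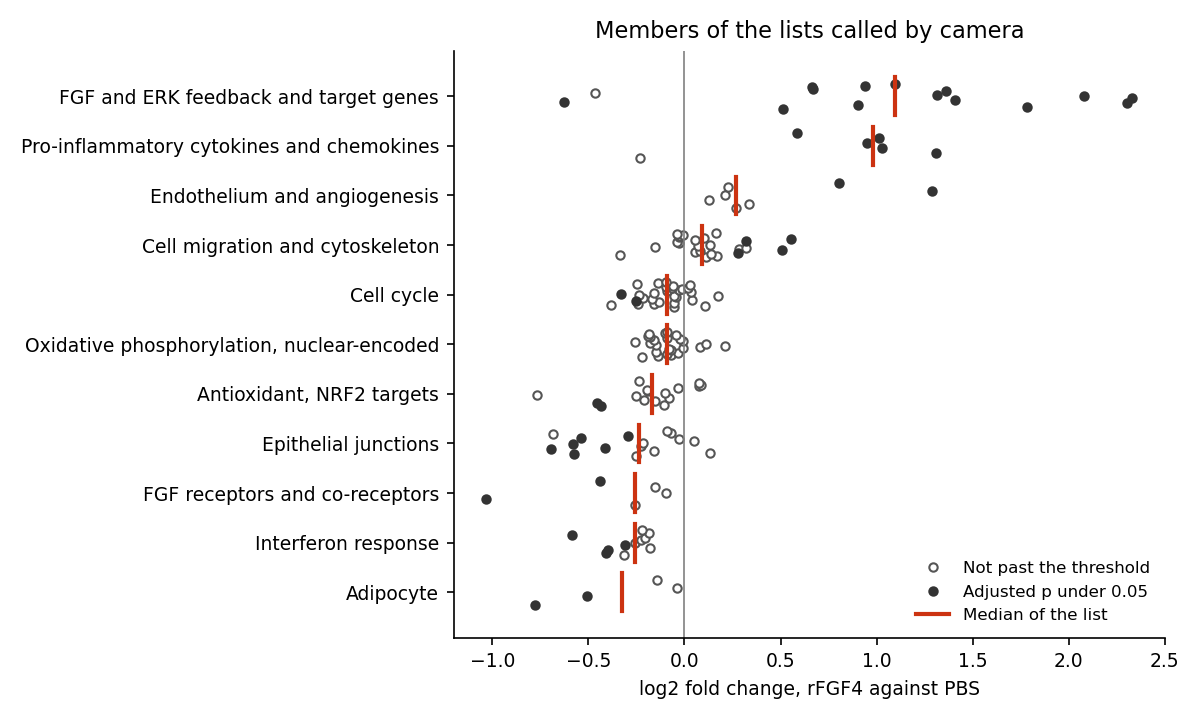
Log2 fold changes, rFGF4 against PBS, of the tested members of the 11 lists called by camera. Filled points passed the threshold (edgeR adjusted p under 0.05), open points did not, and the vertical bars are list medians, from 1.09 for FGF and ERK targets to −0.33 for the adipocyte list.

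The remaining lists were not called. Among immediate early genes, JUN rose by 1.10 (SE 0.08) while BTG2 (−0.72) and EGR1 fell, with 5 of 8 not past (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.52). In the wound-activated keratinocyte list AREG, HBEGF and PLAUR (0.68) rose among 15 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0721). None of 10 tested mesenchymal transition genes passed, and 3 did when adjusted over the list alone (camera adjusted p = 0.0524), VIM having 0.97 (SE 0.32, adjusted p = 0.0943). That list was called under 8 of 22 other settings. Of the basal keratinocyte list KRT15 (−0.56) and LAMB3 (−0.28) fell and ITGA3 (0.40) rose among 14 (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.788). In the Wnt list DKK1 (0.79), WNT7A (0.55) and LRP5 (0.38) rose and WNT10A (−0.86) fell among 9 (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.395). In the TGF beta list CCN2 (1.36), TGFBR2 (0.40) and SMAD3 (0.27) rose and BMP1 (−0.25) fell among 12 (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.442). Of 17 hypoxia and glycolysis genes VEGFA, HK2 (0.97) and PFKP (0.26) rose (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.788); the list median was −0.05 and its mean 0.10. Median and mean also differed in sign in the basal keratinocyte (0.06 and −0.01), hair (0.00 and −0.11) and sebaceous (0.02 and −0.01) lists. PLAUR alone passed among 8 metalloproteinase list members (camera adjusted p = 0.788), P4HA2 (−0.30) among 9 matrix genes (0.788), TGM1 (−0.50) among 6 differentiated epidermis genes (0.237) and SCD (−0.27) among 4 sebaceous genes (0.788). DDIT3 (−0.83) fell among 18 stress response genes (0.406), HIST1H2AG (−0.73) among 4 histone genes (0.0721), and HOXC13 (−0.56) and PADI3 (−0.56) among 5 hair genes (0.442). No member passed in the ribosomal protein (28 tested, 0.788), mitochondrially encoded (13, 0.235), myofibroblast (5, 0.788) and dendritic cell (4, 0.395) lists. Adjusted over the list alone, the counts from the metalloproteinase list onwards were the same except for 1 lower metalloproteinase list member. In the lists too small to test, GPNMB (−0.72) and GSN (−0.32) fell. Adjusted over the list alone, 2 Schwann cell list members were lower, 1 macrophage list member was higher and 1 lower, 1 skeletal muscle list member was higher and 1 dermal fibroblast list member was lower.

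Some calls among these genes ended when a library was left out. TGM1 and LAMB3 did not pass with any 1 library left out, P4HA2 passed only without rFGF4 replicate 4, and GSN only without PBS replicate 3. SCD and PADI3 passed only without rFGF4 replicate 2 or 4, CCN2 only without rFGF4 replicate 1, and TGFBR2 only without PBS replicate 1 or rFGF4 replicate 4. LRP5 did not pass without PBS replicate 1, 2 or 4 or rFGF4 replicate 1 or 3, and PFKP did not without PBS replicate 1, 2 or 3 or rFGF4 replicate 1 or 3. PLAUR did not pass without PBS replicate 1, 2 or 3 or rFGF4 replicate 3, KRT15 without PBS replicate 2 or 4 or rFGF4 replicate 3, and HIST1H2AG without PBS replicate 2 or rFGF4 replicate 1. With limma on TPM, TGM1, SCD, PADI3, CCN2, TGFBR2, LRP5, PFKP and SMAD3 did not pass. With limma on log2(FPKM + 1), the test planned for a table without counts, and with pseudocounts of 0.1 and 0.01, TGM1, TGFBR2 and LRP5 did not pass, nor did CCN2 with the latter pseudocounts. Left-out libraries included, the call was lost under 21 of 28 settings for TGM1, 14 for TGFBR2 and CCN2, 12 for LRP5, LAMB3 and P4HA2, 11 for SCD and GSN, 9 for PADI3 and 7 for PFKP.

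The largest changes by the rule for named genes included genes outside the lists. Beside ETV5, DUSP6, FOSL1, DUSP4 and AREG, the 10 largest rises were in ADAM19 (2.34, SE 0.41), the pseudogene transcript RPSAP52 (2.09, SE 0.18), TMEM171 (1.78, SE 0.14), the cardiac ankyrin repeat protein gene ANKRD1 (1.60, SE 0.19) and RBPJ (1.57, SE 0.32), which encodes the DNA-binding partner of Notch. ADAM19 stood at 39.4 to 40.5 CPM in rFGF4 replicates 1 to 3 and at 10.3 CPM in replicate 4, and RBPJ at 27.4 to 31.1 against 11.4 CPM. The largest fall was in ELF3, an epithelial ETS transcription factor, by 1.96 (SE 0.10, adjusted p = 0.000115), from 228 ± 22.1 to 58.7 ± 6.68 CPM. It was followed by RAB26 (−1.80, SE 0.19), RNF146 (−1.70, SE 0.30), MIR6510 (−1.62, SE 0.25), the tight junction gene TJP3 (−1.60, SE 0.22), MAB21L4 (−1.54, SE 0.21), the death receptor ligand TNFSF10 (−1.49, SE 0.10), the proline oxidase gene PRODH (−1.48, SE 0.15), NECTIN4 (−1.43, SE 0.10) and TENT5B (−1.43, SE 0.17). MIR6510 stood at 0.224 ± 0.059 CPM in the rFGF4 libraries, near the floor and below it in replicate 3, so the size of its fall is uncertain. It lies within the span of KRT15, so its counts are uncertain too, as are those of RPSAP52, whose parent gene is a ribosomal protein gene. The call for RBPJ ended without PBS replicate 2 or 4 or rFGF4 replicate 1 or 3, and with limma on TPM.

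DUSP6 (ENSG00000139318) is listed on chromosome 12 from 89347235 to 89352501, ETV5 (ENSG00000244405) on chromosome 3 from 186046314 to 186110318, VEGFA (ENSG00000112715) on chromosome 6 from 43770184 to 43786487 and ELF3 (ENSG00000163435) on chromosome 1 from 202007945 to 202017183. The build is not given in the sources used here.

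In all, 1157 of 11536 genes passed the edgeR quasi-likelihood test, 633 higher and 524 lower in the libraries labelled rFGF4, with 46 and 45 of them at least 2-fold. The groups did not overlap in 2228 genes (19.3%), against 2.86% by chance. With limma on TPM, 750 genes passed, 324 higher and 426 lower. Leaving out a library gave 732 genes without PBS replicate 1, 601 without PBS replicate 2, 768 without PBS replicate 3, 715 without rFGF4 replicate 1 and 675 without rFGF4 replicate 3. Of 31 lists tested, 11 were called by camera, 4 higher and 7 lower, 0 with an estimated correlation (lowest adjusted p 0.0724) and 16 by fry. Without PBS replicate 4, camera called 7.

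No difference in the library measures was detected between the groups by exact two-sided permutation tests over 70 assignments, of which the smallest possible p is 0.029. The share of FPKM in the 10 most abundant genes was 27.1 ± 0.95% (SD, n = 4) with PBS and 28.2 ± 2.47% with rFGF4 (exact p = 0.429). That in mitochondrially encoded genes was 32.5 ± 1.07% and 33.8 ± 2.93% (exact p = 0.429), and 11504 ± 89.8 and 11410 ± 156 genes were at FPKM of at least 1 (exact p = 0.314). After adjustment over the 5 measures computed, each p was at least 0.536. rFGF4 replicate 4 had the highest mitochondrial share, at 36.7%, and stood farthest along the first principal component. On the second it lay at 24.9 beside PBS replicate 4 at 23.9, with the other libraries at 4.3 or lower.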

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

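The tests of the tissue and keratinocyte lists and of the direction of steps were chosen after the result was seen; the other tests of this part were set beforehand. Groups of 4 libraries were examined for 1 library far from the other 3, in 252 groups covering named genes and library measures. In 9 of them 1 library stood apart, against 12.6 from chance at 1 in 20. Many of these genes were named for a small p or for groups without overlap. The count therefore does not measure how often a library stands apart over all genes. In rFGF4 replicate 4, ADAM19 was low at 10.3 CPM (others 39.4 to 40.5), MAP2K3 high at 118 (99.0 to 101), HBEGF high at 20.2 (16.2 to 16.7) and KIF20A low at 209 (235 to 240). SNAI2 was low in rFGF4 replicate 2, at 31.7 CPM against 67.7 to 71.2. PBS replicate 3 was about as low for SNAI2, at 30.25 CPM against 55.71 to 64.37, but was not flagged. Among the PBS libraries, DUSP5 was low in replicate 1 (4.23 against 6.49 to 6.84), ETV5 low in replicate 2 (3.81 against 5.98 to 6.12), SPARC high in replicate 2 (10.5 against 5.20 to 5.35) and MAPK11 high in replicate 3 (5.91 against 5.10 to 5.19).

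The human genes under mouse labels were weighed first. Mouse reads aligned to a human genome are argued against by zinc finger genes: of 244 numbered ZNF genes without a mouse gene of the same number, 29.5% were at a mean FPKM of at least 1 (exact 95% interval 23.9 to 35.7%), where under 5% was set for that explanation; the share was 57.7% of 227 with such a gene, a gap in the direction the explanation needs, and counterparts under other names were not searched. RNA from tissue round a wound is argued against, as 5.7% of 105 muscle, blood, immune and lymphatic genes reached that level (exact 95% interval 2.1 to 12%), where at least 50% was set for that explanation and under 10% for its absence; lists and bounds were both chosen after the values were seen, the interval reaches past 10%, and over 19 lists of other cell types, dendritic, B cell, endothelial, myofibroblast and Schwann lists among them, it was 15.2% of 256 (11.1 to 20.2%). Human keratinocytes in culture stay open as a candidate source, since the basal keratinocyte list reached 100% with 31.6% of the differentiated list. Keratinocyte markers do not separate a cell line from primary cells, and the design gives no biological explanation to test.

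In 900 of 10803 genes with at least 200 counts on average, 1 library differed by at least 1.62-fold from the other 3 of its group, which lay within 1.32-fold of each other. On simulated counts with counting noise alone, this search recovered 98.5% of 200 planted steps, with 11 false ones. Spread between libraries beyond counting was not simulated, so how many steps it would give is not known. Reads shared between overlapping genes are argued against as the whole cause, because genes with a step overlapped another expressed gene only 1.18 times as often as genes without (95% limits 1.07 to 1.31). Counts moved to assembled features outside the table stay open. Of the steps, 72.4% went down, but the bound of over 60% was set after this value was seen. It therefore cannot decide the question. No biological explanation was tested.

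rFGF4 replicate 4 stood apart from the others of its group, but PBS replicate 4 lay beside it on the second principal component (23.9 and 24.9, others at 4.3 or lower). A gene length trend stays open as a cause: across genes, its deviation from the other 3 libraries of its group correlated with log length at a Spearman rho of −0.416 (genes are not independent), the largest in size of the 8 libraries, with 0.301 in rFGF4 replicate 2 and −0.286 in PBS replicate 4. rFGF4 replicate 4 also held 2.08 times as many steps as the mean of the other 7 libraries, 228 against 109.6. Both predictions were met as set, so the length trend is not excluded. The ratio of steps cannot decide whether steps are a cause. A step is itself a gap between a library and the other 3 of its group, so a library that stands apart can hold more of them whatever the cause. A biological difference between libraries of a group was not tested. The log2 fold changes between the groups correlated with log length across genes at a Spearman rho of −0.107. Without rFGF4 replicate 4, 1166 genes passed, 964 of them among the 1157. The number of genes thus did not rest on this library, but some of the calls did.

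Of the 35 splits of the 8 libraries into 4 and 4, only 1, the labelled one, gave as many as 1157 genes, and the highest of the others gave 5. This argues against a chance assignment of libraries to groups. Chance is not excluded, because 1 of 35 is the smallest share the test can give and the other splits mix the groups. A chance difference between cultures or preparations would give the same result.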

How the results depend on the processing

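DESeq2, the edgeR variants, filterByExpr, counts divided by 4, the fit without step genes, camera with a trend and camera on log2 CPM were chosen after seeing the data, as was keeping limma on log2(FPKM + 1), planned for a table without counts, as an alternative. The count of 1157 genes became 750 with limma on TPM, 1744 with limma and library weights, 1828 with DESeq2 and 1837 at an adjusted p under 0.1. It was 91 at 2-fold or more, and 2228 genes had no overlap between groups; these follow from other thresholds. For the first 3 the cause was not tested. Leaving out 1 library gave 601 to 1166 genes, with fewer samples. The other settings stayed within 1.5 times the count. The 11 lists became 0 with an estimated correlation, and 7 to 12 with 1 library left out. Of lists not called, the mesenchymal transition list was called under 8 of 22 settings, the growth factor and wound-activated keratinocyte lists under 4, the histone list under 2 and the differentiated epidermis, hair, hypoxia and mitochondrially encoded lists under 1. Of 80 genes named by the rule and past the threshold, 51 kept it under every setting run, and 0 changed sign past it. Genes named outside the rule were not followed over the settings. TGM1 lost it under 21 of 28 settings. The library measures kept their side of the threshold.

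With the replicate number as a block, 1013 genes and 9 lists were called, 861 of the genes among the 1157. The migration and adipocyte lists were lost, as were PHLDA1, FABP4, GSN, LAMB3, LRP5, P4HA2, PADI3, SCD, TGFBR2 and TGM1. Deviations of libraries with the same number correlated at 0.138, 0.081, −0.024 and 0.207 for numbers 1 to 4. These values do not settle whether the numbers pair the samples, which the labels do not state. As a hint towards pairing, 3 of 4 numbers correlated best with their own. The replicate 4 libraries of both groups also lay side by side on the second principal component. Robust empirical Bayes and limma without its trend were not run for lists, as camera has no robust option and was run without a trend from the start. What depth limits was not tested, since the simulation, with 26% recovered at 1.5-fold, was run only at the library sizes of the data.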

Other observations

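Terms of the table's own annotation were tested among the called genes, chosen after seeing the data and with the tested genes as background. Genes called higher in the libraries labelled rFGF4 were enriched for terms of ribosome production. Of 156 tested genes annotated to rRNA processing, 45 were called higher, against 8.89 by chance (5.06-fold, hypergeometric adjusted p = 4.92e-17), and 138 of 156 had a log2 fold change above 0, with a median of 0.22. Of 97 ribosome biogenesis genes, 33 were called higher (5.97-fold, adjusted p = 1.34e-14). LYAR rose by 0.84 (SE 0.06), the snoRNA-protein genes NOP56 and NOP58 by 0.63 (SE 0.05) and 0.45 (SE 0.05), the pseudouridine synthase gene DKC1 by 0.54 (SE 0.05), NCL by 0.33 (SE 0.05) and NPM1 by 0.22 (SE 0.05). The enrichment of rRNA processing passed in 28 of 28 other settings, at 4.43 to 8.36-fold. The ribosomal protein list did not move with it (median 0.03, 0 of 28 past). MYC, which drives these genes in many cells, did not pass (−0.46, SE 0.61). Its spread between the rFGF4 libraries, given above, leaves its direction open. Genes are not independent, so these p-values are too small.

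Other terms covered secreted factors and metabolism. Of 45 genes with cytokine activity, 12 were higher (4.68-fold, adjusted p = 0.00159), among them NRG1 (0.71) beside genes named above. Of 19 genes annotated to retinoid metabolism, 7 were lower (7.55-fold, hypergeometric adjusted p = 0.0284), and that enrichment passed in 19 of 28 settings. They were SDC4 (−0.44), LRP1 (−0.65), the retinol dehydrogenase gene RDH10 (−0.41), the retinol receptor gene STRA6 (−0.55), AKR1B10 (−0.58), AKR1C3 (−0.42) and AKR1C1 (−0.41). AKR1C1 and AKR1C3 are close paralogs, so their counts are uncertain. The apical plasma membrane term (19 of 136, 2.86-fold, adjusted p = 0.0284) passed in 9 of 28. Of 2702 GO terms, 26 passed among higher and 5 among lower genes, and of 292 KEGG pathways 2 and 0, the pathway for ribosome biogenesis (24 of 73) leading. In 20 random draws of genes, 0 gave a KEGG call. Such draws do not cover genes that move together, and none were made for GO terms. Chosen after their values were seen, ID1 (−0.58), ID2 (−0.59), ID3 (−0.72), CDKN2B (−0.78), CDKN1B (−0.42) and CYP1A1 (−0.74) fell. Among lower genes, negative regulation of DNA binding, which holds the ID genes, did not pass (6 of 24, adjusted p = 0.172), nor did cyclin-dependent kinase inhibitor activity, which holds the CDKN genes (4 of 11, adjusted p = 0.186).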
